A study of Mus musculus with 2 samples.

How the data were processed

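Cells of the dural meninges, the outer membrane around the brain, were profiled by droplet single-cell RNA sequencing (10x Genomics) in mice at postnatal day 14. There was 1 library from Il33 heterozygous mice (het) and 1 from Il33-deficient mice (KO). Per the labels, both genotypes carry an H2B-mCherry allele at Il33, so the heterozygous animals have 1 intact copy. The labels describe tissue pooled from 5 to 8 mice per genotype and sex, enzymatic digestion at 37 degrees and cell sorting. CD45+CD11b- lymphocytes and gp38+CD31- stromal cells were added to all viable cells in parts of 1:1:2. Shares of cell classes are therefore set in part by the sort.

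The deposited matrices hold unique molecular identifier (UMI) counts per gene and barcode, made by the authors with Cell Ranger 3.0.2 on mm10, per the file headers and the submitters' processing notes. The gene annotation and aligner settings are not given in the sources used here. The het matrix holds 10936 barcodes and 113220628 UMIs, and the KO matrix holds 12046 barcodes and 122426614 UMIs, over 27998 genes with a lowest barcode total of 500 UMIs. A table of annotated cells deposited by the authors holds UMI counts of 19347 genes in 12544 cells. Of 42033638 values above 0, 1673 differ from the matrices. The metadata give each cell's library, its cluster number from integrated data, its total count and a sex label. They also give the percent of UMIs from mitochondrial genes, as deposited by the authors. From the values, annotated cells have 506 to 7500 genes, at most 15.0% mitochondrial UMIs and at most 0.0999% (het) and 0.09998% (KO) hemoglobin UMIs. The filter itself is not given in the sources used here. The sex label equals the presence of an Xist UMI in 12544 of 12544 cells, so shallow female cells can be counted as male. A second table deposited by the authors holds 477 cells of cluster 9 with names (ILC2s, NK, Tcells, gdTcells). ILC2s are group 2 innate lymphoid cells.

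Raw UMIs from the matrices were summed over the annotated cells of each class and library and scaled to all UMIs of that class and library (CPM). With 1 library per genotype there are no replicates, so no test was made and no p-value is given. A difference between the libraries can come from genotype, animals, sort or preparation. Intervals are exact 95% intervals: Poisson for a sum of UMIs, Clopper-Pearson for a share of cells, and the conditional binomial interval for a ratio of Poisson counts. Ratios of cell shares were given the last of these too. It is not exact for them and is too wide where the shares are large. All cover counting error only. Where 0 UMIs were seen, the limit is 3 counts. Shares of cells with a UMI were also given after thinning each cell to 1000 UMIs. Cells with fewer UMIs were left out of the thinned shares, and none of them were ILC2s.

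The authors' names were kept for cluster 9. The other 21 of the 22 deposited clusters were compared with 26 fixed marker lists and called X-like where at least 3 markers were 2-fold above all other cells (pseudocount 5 CPM) and the 10 leading genes did not go against the name. Clusters 1, 2, 6, 10 and 16 were B cell-like, cluster 3 macrophage-like, 4 osteolineage-like, 5 arachnoid barrier-like, 8 blood endothelial-like and 12 mast cell or basophil-like. Cluster 14 was dendritic cell-like, 18 monocyte-like and 20 pericyte or smooth muscle-like. Cluster 15 had 7 of 7 Schwann cell markers, but its leading genes include the oligodendrocyte genes Mog and Mobp, so it is given by number. Clusters 0, 7, 11, 13, 17, 19 and 21 stay unnamed.

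Named genes were taken by a rule. In a class with at least 50 cells per library, a gene needed 100 UMIs over both libraries, a UMI in 10% of the cells of 1 library and a KO/het ratio at least 1.5-fold from 1. Genes were ranked by the bound of the ratio's interval nearest to 1. The first 12 in each direction were taken in ILC2s and the first 5 in other classes. Of these, 2 genes are not reported here, and the figure of ILC2 genes shows the first 11 in each direction. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and T cell receptor segment, Xist, Y-linked and predicted genes were left out of this ranking. Members of 20 gene lists (291 entries) could also be named: IL-33 pathway, ILC2 identity, type 2 effector, ILC2 activation, NF-kB targets, immediate early, heat shock, cell cycle, glycolysis, oxidative phosphorylation, interferon response, MHC class II, regulatory T cell, alternative macrophage, inflammatory myeloid, extracellular matrix, stromal cytokines, IL-4 and IL-13 receptors and targets, hemoglobin and sex-linked. Some genes stand in more than 1 list, so the lists are not independent. A list was measured over its members with at least 20 UMIs in the class. It was described by the median log2 KO/het ratio, a 95% interval from 1000 Poisson draws, and its percentile among 10000 random lists matched on mean expression in 20 bins. The percentile describes these libraries and is no test. A member with 0 UMIs in 1 library was set to 3 counts there. The groups, comparisons, lists, markers, ranking rule and first set of alternatives were chosen before the data were examined.

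Choices made after the data were seen were the scoring behind cluster names, the classes described and the minimum of 0.5 log2 for describing a list outside ILC2s. Clusters 2 and 8 were left out at gene level after reversals that rested on single cells had been seen there. Other classes with such reversals were kept. The counts of moved and reversed list medians and genes given below do not cover clusters 2 and 8. Scrublet was run per library (scanpy, expected rate 6%, 30 principal components). Its automatic threshold marked 3 het and 1 KO cells (0.0504% and 0.0152%). Whether doublets had been removed before is not given in the sources used here. As an added alternative, the cells with the highest scores were left out: 337 het cells (5.66%, score from 0.136) and 383 KO cells (5.81%, score from 0.124). Doublets were not removed from the main values. The other added alternatives leave out, for each gene, the cell with the most UMIs in each library, or leave out ILC2s with an Mki67 or Top2a UMI. The comparison of NF-kB targets with receptor level was first made on all cells of each class. It was made again without cells that held UMIs of 2 or more of 9 macrophage markers, once a B cell-like cluster was seen to carry macrophage RNA. The first version had counted against the receptor as the whole cause, and the second leaves it open.

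The alternatives chosen beforehand were TMM scaling (edgeR 4.0.16), median ratio scaling (DESeq2 1.42.0) and a mean over cells. Others were female or male cells only, cells with 1000 or more UMIs, other gene minima, totals without mitochondrial, ribosomal and hemoglobin genes, and classes called anew from the markers. The 2 scalings shifted the median gene by more than 0.1 log2 only in Tcells (TMM 0.18, DESeq2 0.13) and cluster 18 (TMM 0.10). To compare classes at equal depth, 50 cells per library were thinned to 3000 UMIs in 20 draws, over genes with 50 or more UMIs. The spread of log2 ratios was then set against counting error alone.

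The calculation was tested on simulated data. For ILC2s, 1635 genes were drawn with 200 changed 2-fold: 98.0% of these passed 1.5-fold, 0.767% of unchanged genes did, and 95.7% of intervals held the true ratio. For cluster 11, with 8042 genes, the values were 97.0%, 0.638% and 95.2%. Sums per gene were drawn from a Poisson distribution, which the intervals assume, with no differences between cells. This checks the calculation and not how well the intervals hold where cells of a class differ. Tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scanpy 1.11.5, matplotlib 3.10.9 and R 4.3.3. Gene positions are from GENCODE M21 (GRCm38, the same assembly as mm10).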

Results

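The data are droplet single-cell RNA counts from the dural meninges of mice at postnatal day 14, with 1 library from Il33 het mice and 1 from Il33 KO mice. The authors annotated 5950 of 10936 het barcodes (54.4%) and 6594 of 12046 KO barcodes (54.7%). Median depth was 12746.5 UMIs and 3383 genes per annotated het cell, and 12204.5 UMIs and 3319 genes per annotated KO cell. An Xist UMI was present in 51.0% of het and 45.0% of KO cells, so both sexes are in each library. Levels are given as CPM, the UMIs of a gene summed over the cells of a class and scaled to the total UMIs of that class and library. All ratios are KO over het, with n = 1 library per genotype, and their intervals cover counting error only.

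The first comparison shows the targeted gene in each library. Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718, plus strand, GRCm38) encodes the alarmin IL-33, a cytokine released from stromal and barrier cells. It was highest in the stromal clusters and lower in KO in each of them. In cluster 0 (led by Slc47a1, Cxcl14 and Smoc1) it stood at 110 CPM in het (105 to 114) and 24.5 in KO (22.5 to 26.7), a ratio of 0.224 (0.203 to 0.246). The ratio was 0.160 (0.127 to 0.200) in cluster 7 (led by Pi16, Aldh1a2 and Dpt), 0.217 (0.176 to 0.267) in osteolineage-like cluster 4 and 0.223 (0.178 to 0.279) in arachnoid barrier-like cluster 5. Over these 4 clusters the level was 97.0 in het and 20.4 in KO, a ratio of 0.210 (0.195 to 0.226). Transcript from part of the locus may remain with the mCherry allele, so the KO level is not a measure of intact Il33 RNA.

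Cells with an Il33 UMI made up 69.9% of het and 31.1% of KO cells in cluster 0, at median depths of 19085 and 18094 UMIs. In the B cell-like clusters, used as background, the shares were 2.75% and 0.784%, with median depths from 3934.5 het and 4178 KO UMIs (cluster 1) to 19690 and 19368.5 (cluster 6). After thinning to 1000 UMIs the shares were 7.83% and 2.08% in cluster 0 and 0.311% and 0.0461% in the B cell-like clusters. Macrophage-like cluster 3 held 19.2 and 4.11 CPM, a ratio of 0.214 (0.139 to 0.318). Its thinned shares were 0.225% and 0.456%, from 1 het and 2 KO cells, where the expected shares over draws were 1.11% and 0.258%. Of its cells, 23.3% in het and 24.8% in KO were among those of highest Scrublet score, so expression by macrophages is not shown. No Il33 UMI was seen in ILC2s, which allows up to 3.99 CPM in het and 4.84 in KO.

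**Figure D1:**
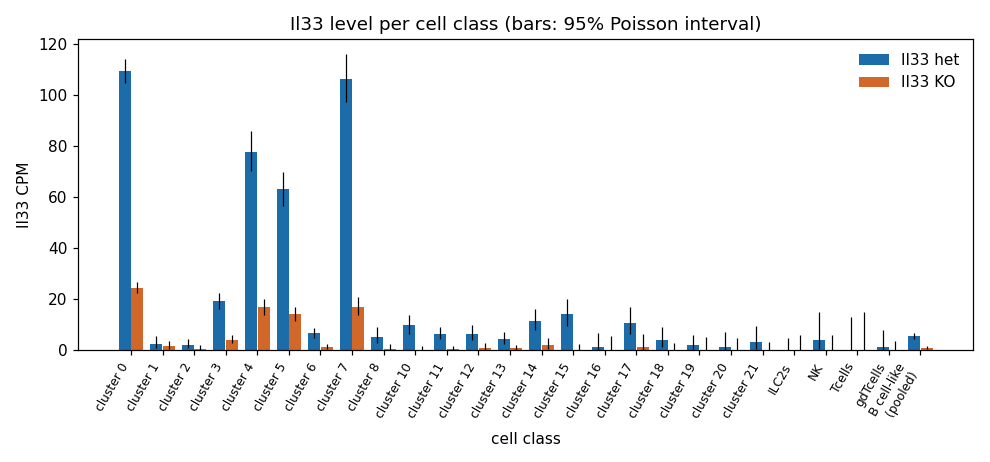
Bars give Il33 CPM in each cell class for the het (blue) and KO (orange) library, with lines for the 95% Poisson interval and the pooled B cell-like clusters as the last pair. Cluster 0 stood at 110 in het and 24.5 in KO, and the B cell-like clusters at 5.44 and 1.01.

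The second comparison asks which cells carry the IL-33 receptor. Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415, plus strand, GRCm38) encodes ST2, the ligand-binding chain of that receptor. ILC2s, tissue lymphocytes that make type 2 cytokines, had the highest level, 537 CPM in het (486 to 592) and 449 in KO (398 to 505), a ratio of 0.836 (0.715 to 0.976). Mast cell or basophil-like cluster 12 had 100 and 79.8, a ratio of 0.797 (0.678 to 0.935). Cluster 11 (led by Cd209a, Ccl17 and H2-Eb1) had 18.5 and 25.4, cluster 3 had 10.2 and 10.4, and cluster 13 (led by Ngp, Camp and S100a9) had 10.8 and 5.67. The B cell-like clusters stood at 1.35 and 1.65, and the authors' Tcells at 122 and 48.4 from 8 and 2 cells.

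An Il1rl1 UMI was present in 92.4% of het and 92.3% of KO ILC2s, at median depths of 10099 and 8565 UMIs, against 0.881% and 1.24% of B cell-like cells at the depths given above. After thinning to 1000 UMIs the ILC2 shares were 45.5% and 30.8%, where the expected shares over draws were 41.9% and 37.3%. At 500 UMIs they were 21.2% and 23.1%. The B cell-like shares were 0.104% and 0.231% at 1000 UMIs, and 0.0518% and 0.231% at 500 UMIs. Cluster 12 had 16.3% and 8.96% at 1000 UMIs, and 10.8% and 5.61% at 500 UMIs. Its unthinned median depths were 17456 and 9946.5 UMIs. Cluster 11 had 2.55% and 1.25% at 1000 UMIs, from 5 het and 3 KO cells, and 29.6% and 31.7% unthinned. Cluster 3 had 0.899% and 0.911% at 1000 UMIs, from 4 cells in each library, and 7.62% and 11.8% unthinned. With the cells of highest Scrublet score in cluster 3 given above, expression of Il1rl1 by its macrophages is not shown.

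The third comparison concerns how many ILC2s each library held. ILC2s made up 66 of 2153 lymphoid cells in het (3.07%, 2.38 to 3.88) and 65 of 2422 in KO (2.68%, 2.08 to 3.41), a ratio of 0.875 (0.612 to 1.25). The difference was within counting error. The sort added CD45+CD11b- cells to both libraries and can set these shares. Within cluster 9, ILC2s were 29.5% and 25.7%, NK 23.2% and 21.3%, Tcells 13.4% and 12.6%, and gdTcells, gamma-delta T cells, 33.9% and 40.3%. When classes were called anew from the markers, ILC2s numbered 82 of 1969 in het and 75 of 2197 in KO, a ratio of 0.820. The ILC2 share of lymphoid cells, KO/het ratio above, was 1.07 in female and 0.716 in male cells.

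Among all annotated cells, cluster 17 (led by the neuronal genes Neurod1 and Elavl2) made up 2.07% of het and 0.955% of KO cells, a ratio of 0.462 (0.336 to 0.631). Cluster 19 (led by the olfactory neuron genes Omp and Gng13) made up 1.41% and 0.622%, a ratio of 0.440 (0.296 to 0.647). Clusters 4 and 1 had higher shares in KO, with ratios of 1.27 (1.11 to 1.46) and 1.16 (1.04 to 1.29). Clusters 8, 15 and 16 had lower ones, at 0.781 (0.651 to 0.937), 0.762 (0.580 to 0.998) and 0.695 (0.527 to 0.912). The sort mix and the dissection can set all of these, and in female cells the share of cluster 17 among all annotated cells, KO/het ratio, was 1.06. In male cells the share of cluster 15 among all annotated cells, KO/het ratio, was 1.29.

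The main comparison is expression in ILC2s, with 66 het and 65 KO cells. Genes of proliferation were lower in KO ILC2s. Mki67, a marker of dividing cells, stood at 249 CPM in het and 46.8 in KO, a ratio of 0.188 (0.123 to 0.279). The topoisomerase gene Top2a had 254 and 50, a ratio of 0.197 (0.130 to 0.289), and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, had 134 and 14.5, a ratio of 0.108 (0.0481 to 0.214). Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, was also lower, at 2791 and 1526, a ratio of 0.547 (0.506 to 0.591). Some genes of transcription factors and cytokines that define ILC2s differed less: Gata3 had a ratio of 0.963 (0.834 to 1.11), Il5 of 1.03 (0.778 to 1.35) and Il13 of 0.808 (0.691 to 0.943). Others, among them Rora, Id2 and Csf2, were lower in KO, with ratios given below.

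Of 17 measured cell cycle genes, 15 were lower in KO ILC2s, 14 of them by at least 1.5-fold, and the median log2 ratio was -2.22 (-2.49 to -1.59). It lay below all 10000 matched random lists, at percentile 0. Birc5, which encodes survivin, had a ratio of 0.161, the Cdk subunit gene Cks1b 0.220, the histone gene H2afx 0.228 and the chromatin protein gene Hmgn2 0.272. The tubulin genes Tuba1b and Tubb5 had ratios of 0.282 (0.210 to 0.373) and 0.370 (0.310 to 0.438), and Stmn1, a microtubule regulator, 0.397 (0.326 to 0.481). Replication genes differed less, with ratios of 1.00 for Pcna, 1.02 for Mcm3 and 0.862 for Mcm5. These UMIs sat in few cells: 16 het and 9 KO cells for Mki67, 15 and 11 for Top2a, and 12 and 5 for Ube2c. Hist1h1b had a ratio of 0.278 from 12 and 3 cells, and of 0.169 without the top cell of each library. The list median was -3.95 in female and -0.56 in male cells (-0.87 to -0.19). The female value lies outside its own interval (-3.90 to -2.87), since a draw of 0 UMIs is set to 3 counts. The ratio among ILC2s with no Mki67 or Top2a UMI was 1.92 for Tuba1b in ILC2s, KO/het ratio, and 1.14 for Tubb5 in ILC2s, KO/het ratio.

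ILC2s with UMIs of 3 or more cell cycle genes numbered 24 of 66 in het (36.4%, 24.9 to 49.1) and 15 of 65 in KO (23.1%, 13.5 to 35.2). The ratio was 0.635 (0.310 to 1.26), so the difference was within counting error. With so few cells the interval is wide and does not exclude a difference. The measure also counts replication genes such as Pcna, which differed less. Median depth was 10099 UMIs in het and 8565 in KO ILC2s. The same measure gave 6.5% and 6.39% in B cell-like cluster 1, at lower depth, and 40.4% and 40.7% in NK.

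NF-kB targets, the genes switched on by the transcription factor that IL-33 and many other signals activate, were lower in KO ILC2s in 12 of 14 measured members. The median log2 ratio was -0.53 (-0.68 to -0.33), at percentile 0.01. Nfkb1 had 945 CPM in het and 591 in KO, a ratio of 0.625 (0.549 to 0.710), Rel 164 and 66.2, a ratio of 0.405 (0.277 to 0.581), and the inhibitor gene Nfkbia 1342 and 911, a ratio of 0.679. Nfkb2 had a ratio of 1.17. Immediate early genes, which respond to many stimuli including tissue digestion, were lower in 15 of 16 members with a median of -0.36 (-0.49 to -0.30), at percentile 0.07. Zfp36, an RNA-decay factor, had a ratio of 0.361 (0.255 to 0.503), while Klf6 had 1.36. The immediate early median was -0.70 in female and -0.01 in male cells. Heat shock genes, another group sensitive to handling, were lower in 7 of 10 with a median of -0.49, at percentile 0.08. It was -0.62 in female and -0.21 in male cells (-0.39 to 0.06).

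Type 2 effector genes had a median of -0.06 (-0.30 to 0.06) with 6 of 11 lower. It was -0.39 in female (-0.58 to 0.09) and -0.23 in male cells (-0.59 to 0.13), over 11 and 9 genes, with intervals that include 0. Csf2, the granulocyte-macrophage growth factor gene, had 249 and 142 CPM, a ratio of 0.571 (0.438 to 0.740), while Il4 had 1.06, Ccl1 0.958 and the neuropeptide gene Calca 0.889. Tnf had a ratio of 2.83, with 18 of its 28 KO UMIs in 1 cell. ILC2 activation genes had a median of -0.15 with 11 of 19 lower. The receptor gene Tnfrsf4 (OX40) had 73.1 and 19.4, a ratio of 0.265 (0.129 to 0.501), Cd69 0.654 and Odc1 0.656, against 1.25 (1.03 to 1.52) for Arg1 and 1.27 for Tnfrsf18. ILC2 identity genes had a median of -0.09 with 8 of 13 lower, among them Rora at 0.759 (0.661 to 0.870) and Id2 at 0.728. The IL-33 pathway stood at -0.06 over 6 genes.

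Ptgs2, which encodes cyclooxygenase-2, was lower in KO ILC2s, at 124 and 12.9, a ratio of 0.104 (0.0438 to 0.214), as was Rrad at 186 and 58.1, a ratio of 0.312. Inflammatory myeloid genes, Ptgs2 among them, had a median of -0.97 (-0.23 in female cells) over 5 measured genes, of which Cxcl2 had a ratio of 0.509 and Tnf that given above. For the inflammatory myeloid genes in ILC2s, median log2 KO/het was 0.30 with a minimum of 1 UMI and 0.05 without cells that held an Mki67 or Top2a UMI. The glycolysis median was -0.17, oxidative phosphorylation -0.11, regulatory T cell 0.03, IL-4 and IL-13 receptors and targets 0.25, hemoglobin 0.35 and sex-linked -0.42. The interferon response median was -0.25 over 7 genes, with -0.97 in female and 0.35 in male cells.

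Higher in KO ILC2s were genes typical of stromal cells. Extracellular matrix genes were higher in 11 of 11 measured members, 10 of them by at least 1.5-fold, with a median of 1.02 (0.84 to 1.31) at percentile 100. The collagen genes Col1a1 (194 and 399 CPM), Col1a2 (158 and 366) and Col3a1 (79.8 and 161) had ratios of 2.05 (1.67 to 2.54), 2.32 (1.85 to 2.92) and 2.02. The matrix protein gene Sparc had 2.28, the growth factor gene Igf2 2.78 and its binding protein gene Igfbp5 2.71. In B cell-like cluster 1, which should lack these genes, the list was higher too, with a median of 0.63 (0.52 to 0.72). R3hdm1 had 38.6 and 115, a ratio of 2.97 (1.91 to 4.75), the lymphocyte GTPase gene Gimap3 2.41 (1.78 to 3.30), and the metabolic regulator gene Txnip 2.30. Ccrl2 had 2.36. Il2, a T cell growth factor gene, had a ratio of 1.95 (1.39 to 2.75), with 45 of 93 KO UMIs in 1 cell and a ratio of 1.21 without the top cell of each library.

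**Figure D2:**
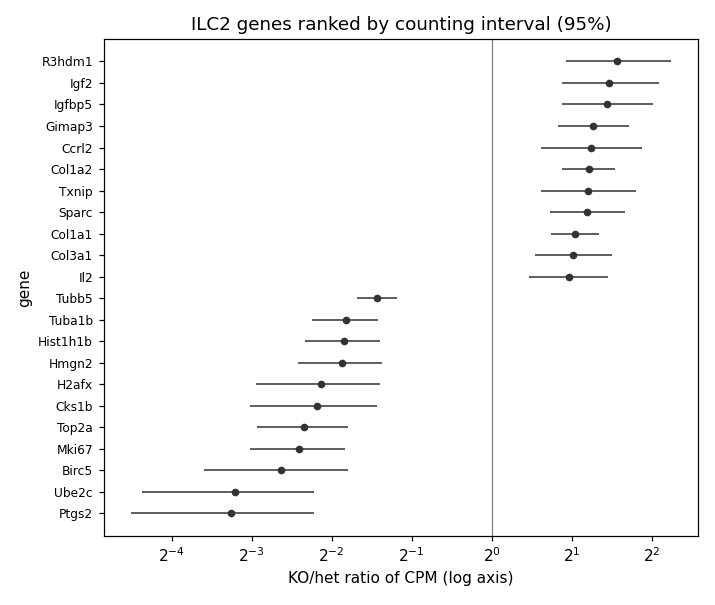
Points give the KO/het ratio of CPM on a log axis for the first 11 genes ranked higher and the first 11 ranked lower in KO ILC2s, with lines for the 95% counting interval. Ratios ran from 0.104 for Ptgs2 to 2.97 for R3hdm1.

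Expression in other classes was compared in the same way. In macrophage-like cluster 3 (446 het and 440 KO cells), the chemokine genes Cxcl2 and Cxcl1 and the NF-kB targets were lower in KO. The neutrophil chemokine gene Cxcl2 had 1938 CPM in het and 294 in KO, a ratio of 0.151 (0.145 to 0.159), with UMIs in 309 and 131 cells. Cxcl1 had a ratio of 0.181, the fatty acid receptor gene Gpr84 0.175, and Tnfaip3, a feedback inhibitor of NF-kB, 0.259 (0.220 to 0.303). All 15 NF-kB targets were lower, with a median log2 ratio of -0.60 (-0.73 to -0.49). Among them were Nfkbia, at 1131 and 404 with a ratio of 0.357 (0.342 to 0.372), and Nfkbiz, at 0.397. Inflammatory myeloid genes were lower in 11 of 14 with a median of -0.63. Tnf had a ratio of 0.564 and Il1b of 0.645. Cell cycle genes were lower in 16 of 18 with a median of -0.93, Ube2c having 49.2 and 12.3 and Mki67 a ratio of 0.337. The share of cells with UMIs of 3 or more cell cycle genes was 49.6% in het and 46.1% in KO. Its ratio was 0.931 (0.766 to 1.13), within counting error. Type 2 effector genes had a median of -0.72 over 8 genes, with -0.06 in female and -1.51 in male cells. Regulatory T cell genes, 5 of them measured, had -1.15, with -0.21 in female cells. Markers of resident macrophages differed less, with ratios of 1.03 for the mannose receptor gene Mrc1 and 1.34 for Lyve1, and the alternative macrophage median was 0.12. Higher in KO were genes that 1 cell mostly carried: Bglap at 4.92 (312 of 407 UMIs in 1 cell, 1.25 without the top cells) and Spp1 at 2.84 (535 of 958, 1.41 without). Acp5 had 3.08 (2.14 without), S100a4 1.94 (1.64 without) and Ly6d 1.71 (2.08 without).

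Cluster 11 (196 het and 240 KO cells), led by Cd209a and H2-Eb1, had lower levels of several of the same genes. Cxcl2 had 1036 and 139, a ratio of 0.134 (0.124 to 0.144), Cxcl1 0.117, Gpr84 0.139, the microRNA host gene Mir155hg 0.125 and the interferon-induced chemokine gene Cxcl10 0.171. Tnf had 137 and 36.3, a ratio of 0.265, and Ccl17, a chemokine for CCR4+ T cells, 258 and 77.5, a ratio of 0.301 from 25 and 24 cells. All 15 NF-kB targets were lower with a median of -0.59 (-0.71 to -0.44), Icam1 having a ratio of 0.241. The inflammatory myeloid median was -0.71. The 6 measured type 2 effector genes, which include Tnf and the regulatory cytokine gene Il10 (0.158), were all lower with a median of -2.07, with -1.66 in female and -3.19 in male cells. Stromal cytokines had a median of -0.52. Extracellular matrix genes had -0.61, with -0.14 in female cells (-0.27 to 0.02) and -1.54 in male cells. For the extracellular matrix genes in cluster 11, median log2 KO/het was 0.0661 without the cells of highest Scrublet score. MHC class II genes were higher, with a median of 0.29 (H2-Aa and Cd74 both 1.24). Siglech, a marker of plasmacytoid dendritic cells, had 59.1 and 117, a ratio of 1.98. Chchd10 had 2.20, Upb1 2.19 and Cd72 2.10. Ptgds had 12.8, with 1823 of 3087 KO UMIs in 1 cell and 5.94 without the top cells.

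Across 22 classes, the NF-kB median was lowest in clusters 3 and 11. It was -0.56 (-0.64 to -0.26) in B cell-like cluster 6, where cells with UMIs of 2 or more of 9 macrophage markers carried most of it: without them it was -0.14 (-0.29 to -0.01). It was -0.22 in cluster 0 and 0.35 in cluster 15 (with the myelin genes Mag and Mog among its leading genes). Without such cells these came to -0.07 (-0.24 to 0.01) and 0.12 (-0.14 to 0.43), with intervals that include 0. Over all cells, intervals also lay below 0 in ILC2s (median -0.53), cluster 13 (-0.38), cluster 18 (-0.34), NK (-0.26) and gdTcells (-0.18). The gdTcells interval included 0 without cells holding macrophage RNA. Only cluster 15 had an interval above 0, and in classes not named here it included 0.

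**Figure D3:**
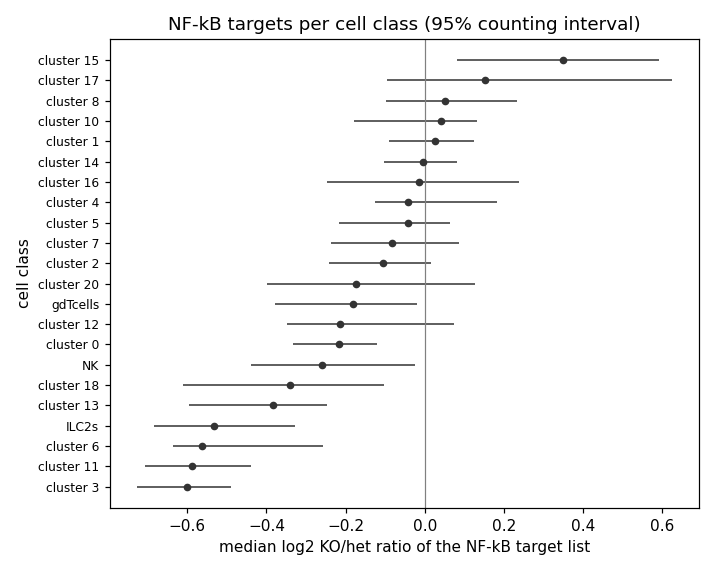
Points give the median log2 KO/het ratio of the NF-kB targets in each of 22 cell classes, with lines for the 95% counting interval. The medians were -0.60 in cluster 3, -0.59 in cluster 11 and -0.53 in ILC2s.

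In mast cell or basophil-like cluster 12 (166 het and 214 KO cells), the cytokine genes Il1b and Il6 were also lower in KO. Il1b had 138 and 15.8, a ratio of 0.114 (0.0852 to 0.151) and 0.0648 without the top cells, Il6 80.6 and 11.4, a ratio of 0.141, and Irg1, an itaconate-producing enzyme, 0.0783 (0.0486 without the top cells). Cxcl2 had 0.203 (0.109 without the top cells) and Il13 54.7 and 20.2, a ratio of 0.370. Inflammatory myeloid genes were lower in 12 of 13, median -1.05, and type 2 effector genes in 7 of 8, median -1.51. Ttr had a ratio of 0.282, but 13952 of its 13998 het UMIs sat in 1 cell and the ratio without the top cells was 19.9. Higher in KO were the matrix genes Fn1 (15.8 and 116, a ratio of 7.35), Matn4 (13.2), Col3a1 (5.27) and Mfap5 (7.26, and 4.22 without the top cells), and the gelatinase gene Mmp9 (10.2, from 4 and 24 cells, and 21.6 without the top cells). The extracellular matrix median was 1.77 over 20 genes. For the interferon response genes in cluster 12, median log2 KO/het was 1.41 in all cells, 2.10 in female, 0.10 in male cells and 0.72 without the top cells. For the MHC class II genes in cluster 12, median log2 KO/het was 1.76, with 0.74 in female and 2.00 in male cells, and 0.70 without the top cells, 512 of 846 KO Cd74 UMIs being in 1 cell. The cluster also differed in depth, with medians of 17456 het and 9946.5 KO UMIs, in mitochondrial share, with means of 6.66% and 8.70%, and in cells with an Il1rl1 UMI, at 37.95% and 18.7%. Mast cells or basophils called anew from the markers numbered 76 in het and 61 in KO. The leading genes of cluster 12 also include Prtn3 and Mpo, the latter a member of the neutrophil marker list. The cluster may thus hold more than 1 cell type, and a different mix in each library was not told apart from changes within cells.

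NK (52 het and 54 KO cells) had lower levels of the chemokine genes Ccl4 and Ccl5 and of the granzyme genes Gzma and Gzmb in KO. Ccl4 had 360 and 42.2, a ratio of 0.117 (0.0755 without the top cells), Ccl5 4354 and 1893, a ratio of 0.435, Gzma 0.532 and Gzmb 0.239. In male cells, Gzmb in NK, KO/het ratio, was 1.40 and Ccl5 in NK, KO/het ratio, was 1.02. Interferon response genes were lower in 8 of 9 with a median of -0.83 (-1.26 to -0.56), Cxcl10 having 0.240, and 0.469 without the top cells. Extracellular matrix genes were higher in 16 of 16, median 2.15, with 2.78 in female and 1.33 in male cells. For the extracellular matrix genes in NK, median log2 KO/het was 0.04 without the cells of highest Scrublet score. Lum had 25.8 (153 of 166 KO UMIs in 1 cell), Dcn 12 (286 of 463 in 1 cell), Mfap4 7.91 (267 of 377 in 1 cell) and Ogn 12.8. Without the top cells the ratios were 3.36 for Lum, 5.5 for Dcn and 3.05 for Mfap4. For Lum in NK, KO/het ratio was 0.566 without the highest Scrublet scores, and for Dcn in NK, KO/het ratio was 0.741.

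In gdTcells (76 het and 102 KO cells), several genes that B cells express were higher in KO: Cd79a had a ratio of 10.8 (4 and 15 cells), Vpreb3 9.32, Ly6d 6.41 (2 and 13 cells), Cd74 5.46 (11 and 28 cells) and Chchd10 5.32. The het levels of Cd79a, Vpreb3 and Ly6d rest mostly on 1 cell (7 of 10, 10 of 13 and 12 of 13 UMIs), and the ratios without the top cells were 31.1, 32.8 and 68.4. The MHC class II median was 2.41 over 4 genes, and 1 het and 11 KO cells were among those of highest Scrublet score. For Cd74 in gdTcells, KO/het ratio was 0.833 without those cells. Lower were Kdm2b (0.443), Cdkn2c (0.509), Odc1 (0.613), Scp2 (0.656) and Apoe (0.591, with 78 of 141 het UMIs in 1 cell and 1.10 without the top cells). For Apoe in gdTcells, KO/het ratio was 1.92 in male cells. The inflammatory myeloid median was 0.93 over 7 genes and the extracellular matrix median 0.65 over 14. For the inflammatory myeloid genes in gdTcells, median log2 KO/het was 0.07 as a mean over cells.

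Of the stromal classes, cluster 0 (984 het and 1155 KO cells) had less Atf3, a stress-response transcription factor gene, in KO. It had 375 and 179, a ratio of 0.478 (0.460 to 0.497), the neurotrophin gene Bdnf 0.434, Ppm1n 0.338 and the myelin gene Mbp 0.460 (0.344 without the top cells). Immediate early genes were lower in 17 of 17, median -0.53, with -0.20 in female and -0.79 in male cells. The medians were -0.52 for cell cycle (-0.14 female, -0.84 male), -0.64 for inflammatory myeloid (-0.18 female, -0.84 male) and -0.57 for type 2 effector genes. Angptl7 (2.06), Pmvk (1.75), the cartilage matrix gene Comp (1.72), Ptgds (1.63) and Scara5 (1.62) were higher.

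In cluster 7 (264 het and 316 KO cells), interferon-induced genes were lower in KO: Ifit1 had 63.3 and 9.46, a ratio of 0.149 (0.109 to 0.201), Ifit3 0.294 and Isg15 0.362. The interferon response median was -0.63 with 16 of 17 lower. It was -0.97 in female and -0.32 in male cells. H2-Aa had a ratio of 0.280 with 173 of 215 het UMIs in 1 cell, and 0.989 without the top cells. For the MHC class II genes in cluster 7, median log2 KO/het was -1.43, with -2.09 in female and -0.20 in male cells, and 0.34 without the cells of highest Scrublet score. For the alternative macrophage genes in cluster 7, median log2 KO/het was -0.87, with -0.36 in female cells, and -0.12 without the top cells. The bone morphogenetic protein gene Bmp3 (9.95, from 4 and 36 cells), the retinoic acid enzyme gene Aldh1a3 (7.75), Phex (7.49), Pcolce2 (7.04) and the collagen gene Col6a6 (6.78) were higher.

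Arachnoid barrier-like cluster 5 (295 het and 372 KO cells) had more Ptgds, the prostaglandin D2 synthase gene, in KO, at 7802 and 14964, a ratio of 1.92 (1.90 to 1.94). A Ptgds UMI was present in 54.2% of het and 62.9% of KO cells, with up to 5874 and 8025 UMIs in 1 cell. Arachnoid barrier cells called anew from the markers numbered 167 in het and 273 in KO. A different mix of cells in each library was not told apart from changes within cells. Cyp2f2 had 2.96 and Inmt 2.37. S100a8 (2.60, with 644 of 748 KO UMIs in 1 cell) and S100a9 (2.05, with 697 of 827) came to 1.13 and 0.988 without the top cells. The cartilage collagen genes Col2a1 (139 and 24.7, a ratio of 0.178) and Col9a1 (0.219) were lower, as were H2-Ab1 (0.195) and H2-Aa (0.209). For H2-Aa in cluster 5, KO/het ratio was 1.59 in male cells. The interferon response median was -0.76 with 16 of 18 lower, -0.97 in female and 0.07 in male cells. The MHC class II median was -1.80 over 6 genes, with -2.03 in female and -0.13 in male cells. The type 2 effector median was 0.72 over 4 genes, with 0.02 in female cells (-0.62 to 0.54), and the alternative macrophage median 0.65 over 8. For the type 2 effector genes in cluster 5, median log2 KO/het was -0.27 with a minimum of 1 UMI.

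Osteolineage-like cluster 4 (360 het and 507 KO cells) had more Mmp9 in KO, at 41.1 and 247, a ratio of 6.0 (543 of 1731 KO UMIs in 1 cell, 4.67 without the top cells). H2-Aa had 4.11, H2-Eb1 3.16, Pcolce2 3.45 and Cd74 2.82. The first 3 had 2.15, 1.64 and 2.01 without the top cells. The MHC class II median was 1.43 over 6 genes, with 0.42 in female and 2.20 in male cells. For the MHC class II genes in cluster 4, median log2 KO/het was 0.27 without the cells of highest Scrublet score. Lower were the vasodilator peptide gene Adm (0.369), the vitamin D receptor gene Vdr (0.437), the ceruloplasmin gene Cp (114 and 61.1, a ratio of 0.535) and the complement gene C1qb (0.437, and 0.662 without the top cells). The alternative macrophage median was -0.87 over 4 genes.

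To set classes side by side, the spread of log2 ratios beyond counting error was measured at equal depth and cell number. The excess SD was 0.392 in cluster 12, 0.333 in cluster 15, 0.240 in cluster 11, 0.232 in cluster 13, 0.226 in cluster 7, 0.221 in ILC2s, 0.218 in cluster 20, 0.212 in cluster 0 and 0.204 in cluster 3. It was 0.175 in NK and 0.149 in gdTcells, against 0.126 to 0.159 in the B cell-like clusters. With 25 cells per side it was 0.213 between genotypes in ILC2s, against 0.180 between parts of the het and 0.155 between parts of the KO library. In cluster 12 it was 0.454, against 0.315 and 0.377. The values lay closer together in cluster 15, with 0.344 against 0.321 and 0.313, and in NK, with 0.188 against 0.182 and 0.183. In clusters 5, 6, 8, 13, 14, 17 and 18 the value between genotypes was lower than at least 1 of the values within a library, as in cluster 13, with 0.289 against 0.293 and 0.329. The excess SD thus includes differences between cells of the same library, and the order of classes is not an order of genotype differences.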

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

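All comparisons in this part were chosen after the list medians had been seen. Among the classes described gene by gene, 6 lists had a median log2 KO/het ratio of -0.5 or less in 1 class and 0.5 or more in another, with both counting intervals excluding 0. Other lists had smaller differences in sign between classes. The difference between those classes was not tested. Type 2 effector genes stood at -2.07 in cluster 11 and 0.72 in arachnoid barrier-like cluster 5. Interferon response genes stood at -0.83 in NK and 1.41 in mast cell or basophil-like cluster 12. MHC class II genes stood at -1.80 in cluster 5 and 2.41 in gdTcells. Alternative macrophage genes stood at -0.87 in osteolineage-like cluster 4 and 0.65 in cluster 5. Inflammatory myeloid genes stood at -1.05 in cluster 12 and 0.93 in gdTcells. Extracellular matrix genes stood at -0.61 in cluster 11 and 2.15 in NK. Several of these medians rest on 1 cell, on cells of high Scrublet score or on 1 sex, as given with them above.

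Barcodes that the authors left out of their annotation were not used in the comparisons. Of 4986 such het barcodes, 8 (0.160%) held UMIs of both Il1rl1 and Gata3, and of 5452 KO barcodes 10 did (0.183%). Their median share of mitochondrial UMIs was 5.72% in het and 18.5% in KO, and their median depth 10417 and 5588.5 UMIs. Among annotated cells, 75 het (1.26%) and 68 KO cells (1.03%) held both.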

How the results depend on the processing

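The settings without the highest Scrublet scores, without the top cell of each library, and without ILC2s that held an Mki67 or Top2a UMI were chosen after seeing the data. Of 579 values of gene list medians, 479 stayed within the counting interval of the main value, 93 moved beyond it and 7 reversed, which is counted only where the main interval excludes no difference. For single genes these were 903, 240 and 17 of 1160, for shares 175, 15 and 2 of 192, and for other values 22, 19 and 0 of 41. These totals do not measure robustness. The automatic Scrublet threshold and the minimum of 1000 UMIs each moved none of 50 list medians and 114 genes, the former leaving out almost no cells. All 10 unthinned shares moved, being set against thinned ones. The list and gene totals cover only the classes described gene by gene, without clusters 2 and 8. Female and male cells alone moved the most single genes (70 in female and 65 in male cells, with 4 more reversed in male cells). No paired analysis was possible because each genotype has 1 library and no result comes from a test. The comparison at 100 cells per library was not run for ILC2s, which number 66 and 65. The cause was not tested for any change below, except where cells were left out by construction.

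Among the main results, cell cycle genes in ILC2s, median log2 KO/het, came to -2.86 without the highest Scrublet scores, -2.67 without the top cells, -3.95 in female and -0.56 in male cells. Members at 0 UMIs are set to 3 counts, which can lie above members with 1 or 2 counts. The type 2 effector genes in ILC2s, median log2 KO/het, came to -0.39 in female cells. NF-kB targets genes in cluster 3, median log2 KO/het, came to -0.76 as a mean over cells. NF-kB targets genes in cluster 11, median log2 KO/het, came to -0.73 as a mean over cells, -0.38 in female and -0.80 in male cells. Il33 in cluster 0, KO/het ratio of CPM, was 0.266 as a thinned share. For cells with an Il1rl1 UMI in ILC2s, het, percent was 21.2 at 500 UMIs and 92.4 unthinned, and for cells with an Il1rl1 UMI in ILC2s, KO, percent was 92.3 unthinned. At 500 UMIs the KO share was 23.1%, above the het share.

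These values reversed. In male cells: interferon response genes in ILC2s, median log2 KO/het, 0.35; interferon response genes in cluster 5, median log2 KO/het, 0.0749; H2-Aa in cluster 5, KO/het ratio, 1.59; Apoe in gdTcells, KO/het ratio, 1.92; Gzmb in NK, KO/het ratio, 1.40; Ccl5 in NK, KO/het ratio, 1.02; share of cluster 15 among all annotated cells, KO/het ratio, 1.29. In female cells: share of cluster 17 among all annotated cells, KO/het ratio, 1.06. With a minimum of 1 UMI: inflammatory myeloid genes in ILC2s, median log2 KO/het, 0.30, and type 2 effector genes in cluster 5, median log2 KO/het, -0.27. Without cells holding Mki67 or Top2a, the inflammatory median in ILC2s was 0.0530, with 1.92 for Tuba1b in ILC2s, KO/het ratio, and 1.14 for Tubb5 in ILC2s, KO/het ratio. Without the highest Scrublet scores: Cd74 in gdTcells, KO/het ratio, 0.833; Lum in NK, KO/het ratio, 0.566; Dcn in NK, KO/het ratio, 0.741; extracellular matrix genes in cluster 11, median log2 KO/het, 0.0661; Ttr in cluster 12, KO/het ratio, 75.3; H2-Aa in cluster 7, KO/het ratio, 1.63; MHC class II genes in cluster 7, median log2 KO/het, 0.34; S100a8 in cluster 5, KO/het ratio, 0.314; S100a9 in cluster 5, KO/het ratio, 0.299. Without the top cells, Apoe came to 1.10, Ttr to 19.9 and S100a9 to 0.988, and as a mean over cells Ttr came to 1.12.

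For NF-kB targets genes in ILC2s, median log2 KO/het stayed between -0.68 and -0.45 in the settings run. The share of cluster 12 among all annotated cells, KO/het ratio, whose interval includes 1 (0.945 to 1.43), was 1.16 and came to 0.724 when called anew from the markers. The ILC2 share of lymphoid cells moved by less than its interval in each setting. With 66 and 65 ILC2s, cell number limits this class: a gene with 100 UMIs over both libraries had a ratio interval as wide as that of R3hdm1, 1.91 to 4.75.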

Other observations

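Of the tests in this part, those of doublets for the cell cycle pattern and all 3 for the NF-kB pattern were chosen after the result was seen. Cell cycle genes did not move one way across the classes not described above. Cluster 15, with the myelin genes Mag and Mog among its leading genes, had them higher in KO, with a median log2 ratio of 3.41 (2.96 to 3.76) and 18 of 18 members higher, and an Xist UMI in 63.1% of its het and 30.1% of its KO cells. Dendritic cell-like cluster 14 had a median of 1.02 (0.78 to 1.10). Cluster 13, led by the neutrophil granule genes Ngp and Camp, had -0.86 with 18 of 18 lower. Monocyte-like cluster 18 had MHC class II genes higher, with a median of 3.13 over 6 members. How many cells carry these differences was not counted.

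Cell cycle genes were lower in KO ILC2s. The sampling of few cycling cells stays open: the share of ILC2s with 3 or more such genes had a ratio of 0.635 with an interval that includes 1. That share differed less than the list median did, so it does not show that sampling accounts for the whole of it. A shortage of cycling cells of 1 sex cannot be told apart from such sampling, with ratios of 0.580 in female and 0.680 in male cells and few cells in each. Doublets with cycling cells of other classes stay open: the median was -2.86 without the highest Scrublet scores, but these included 0 het and 1 KO ILC2s, so leaving them out could not lower the het level. A genotype effect on ILC2 proliferation remains an untested hypothesis.

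NF-kB targets were lower in KO in macrophage-like cluster 3 and in cluster 11. Immediate early genes were lower in 50% of the 22 classes (11) and higher in 7. This argues against a handling difference that acted on that list in every class alike. It does not settle the question for the NF-kB list itself. That list had intervals below 0 in several classes besides clusters 3 and 11, as given above. Doublets are argued against in cluster 3 by a median of -0.56 without the highest Scrublet scores. That value does not cover cluster 11, where 11.2% of het and 7.08% of KO cells were among those scores. Loss of IL-33 signalling through the receptor on the same cells as the whole cause cannot be told apart from other differences between the libraries: once cells with macrophage RNA were left out, no class at or below the B cell-like Il1rl1 level had a median below -0.20 (cluster 17), but cluster 12, with 100 Il1rl1 CPM, had -0.21 over all its cells with an interval that includes 0 (-0.35 to 0.07). Cluster 12 also differed between the libraries in depth and in its share of cells with an Il1rl1 UMI, as given above. In cluster 3, Il1rl1 expression by the macrophages themselves is not shown. Genotype, and handling that acted on macrophages more than on other cells, remain open and untested.

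Extracellular matrix genes were higher in KO ILC2s. With each cell capped at 3 UMIs per gene the median was 0.74 and 11 of 11 members were higher. This argues against a few cells with many matrix UMIs as the only source. Doublets with stromal cells stay open, since the cap limits what a doublet adds but does not remove it. In NK the capped median was still 0.40 (0.11 to 0.74), although the uncapped one was near 0 without the highest Scrublet scores. More free stromal RNA in the KO library may be the source, but cannot be told apart from other sources: the capped median was 0.59 to 0.73 in 4 of the B cell-like clusters and 0.23 in cluster 10. Expression by ILC2s themselves was not tested.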
